A study of Mus musculus with 4 samples.

How the data were processed

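RNA was measured in mouse leukaemic cells taken from the spleens of transplanted mice. Per the labels' protocols, bone marrow stem cells of wild-type or Tet2 knockout donors had been made leukaemic with NRAS and AE9a, a truncated AML1-ETO fusion. In culture the cells received the cytokines SCF, IL-3 and IL-6, and were selected with G418 and puromycin. Recipients carrying CD45.1 were 6 to 8 weeks old and were irradiated with 900 cGy, and CD45.2 cells, which carry the donor form of this surface protein, were enriched from the spleen. Libraries were made with a stranded mRNA kit from total RNA extracted with QIAzol, per the labels. The 4 libraries fall into 2 groups of 2 by their titles and genotype labels: WT and Tet2 KO.

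The values are TPM (transcript abundance scaled to a fixed total per library) as deposited by the authors, with each library summing to 1000000 over 24589 rows. STAR, an aligner, RSEM, which estimates transcript abundance, and the mm10 build are named per the submitters' processing notes, without versions; the gene annotation is not given in the sources used here. The rows include 92 ERCC spike-in RNAs, left out of all tests, and Rn45s, a ribosomal RNA precursor. A date stands in place of a name in 27 rows, 18 of which were tested and none of which is named. Of the 24497 mouse rows, 23720 matched a symbol in the GENCODE annotation of the same genome build, which gave the coordinates. They are counted from 1.

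TPM does not state depth. Depth was estimated from the low values of genes with a single annotated transcript of 600 to 2500 nt: multiplied by the length minus 200 nt, they fall on multiples of the value of 1 read. In each library 78.1% to 80.5% of these values lay within 0.2 of a whole multiple. The resulting depths are approximate, in units of M (10 to the power 6), at 20.7 and 18.6 M reads for the WT libraries and 23.2 and 23.8 M for the Tet2 KO libraries. No interval from read counts is given, since these reads were not counted directly.

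Before libraries were averaged, the members of each group were compared over single-transcript genes with more than 20 estimated reads in the pair. The variance between the WT libraries was 1.17 times that of read sampling (robust estimate, 4670 genes), and 29 genes lay beyond 5 SD. The ratio was 8.40 for the Tet2 KO libraries (4881 genes, 1006 beyond 5 SD). Without robust estimation the ratios were 2.11 for WT and 54.5 for Tet2 KO. Over the genes with the most estimated reads the robust ratios were 1.90 and 235, so abundant genes differed more than by sampling in WT too. The WT libraries were therefore averaged and counted as 1 sample (n = 1), against 2 Tet2 KO samples (n = 2). This departs from the design fixed before the data were examined, which took all 4 libraries as samples. The change was made after seeing the data, and after the number of calls in both fits had been seen; it gives fewer calls. The design as fixed called 3520 genes higher and 4517 lower. With 1 residual degree of freedom, all spread comes from the Tet2 KO libraries, and the lone WT sample is assumed to vary as they do. The labels do not say whether libraries of a group came from separate mice, so p-values measure only the spread between these libraries, which may be technical.

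Differences were tested with limma 3.58.1 in R 4.3.3 on log2(TPM + 1), with moderated variances, an abundance trend and robust estimation. Genes needed at least 1 TPM in at least 2 libraries, which left 11919. Adjusted p-values are Benjamini-Hochberg values over these genes, two-sided, with a threshold of 0.05. Fold changes on the log2(TPM + 1) scale understate the change of low genes. The error of a log2 change is its standard error from limma, and other errors are SDs over the 2 Tet2 KO libraries.

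Gene lists had been fixed before the data were examined. Of 34 pathway and cell type lists, 31 had at least 5 tested members and were tested against all other genes with limma's camera at a preset correlation of 0.01, adjusted over the lists. Camera with an estimated correlation was run beside it. Limma's fry, which asks whether members of a list move one way on balance without comparing them with other genes, was also run. Members of 3 transgene-related loci and 5 sex-linked genes served as checks.

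Genes are named by a rule fixed in advance, which chose 115, of which 2 are not reported here. It takes Tet1, Tet2 and Tet3; the 10 largest changes in each direction among genes past the threshold, with the groups apart in every library and a mean of at least 2 TPM in the higher group, leaving out predicted gene names; up to 4 members with the smallest p in the direction of each called list and 1 in the other direction; and 20 genes of antigen presentation, immune ligands, homing, progenitors and the transgenes. Other genes named were chosen after their values were seen, or are members of the lists.

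The gene and list tests were run on simulated TPM with known changes (11919 genes, 200 of them changed, 10 runs, WT as 1 sample). They recovered 1.2% of 1.5-fold changes, 17.8% of 2-fold, 90.8% of 4-fold and 98.6% of 8-fold changes, and 4.23% of calls were false. In these runs changes near 2-fold were thus often missed. The data hold 5811 calls, far more than the 200 simulated changes, which loosens the Benjamini-Hochberg cutoff. The recovered shares may therefore be too low for these data, by an unknown amount. A list moved by 2-fold was found in 10 of 10 runs, and an unmoved list in 0. Noise was drawn for each gene on its own. False list calls from members that vary together could therefore not appear in these runs. Camera with an estimated correlation found the moved list in 0 of these runs. With WT as 1 sample and 1 residual degree of freedom it thus had little power for changes of that size. A list that did not pass it is therefore not shown to be unchanged.

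Alternatives fixed in advance were quantile normalization, median centring, limma without trend and robust estimation, no filter, a filter of 5 TPM, a pseudocount of 0.1, leaving out each library, fold thresholds and an adjusted p under 0.01. A block for the replicate number had also been fixed, but it needs both WT libraries, and that combination was chosen after seeing the data. Scaling to the ERCC total and rescaling without ERCC and Rn45s were also added after seeing the data. Figures were drawn with matplotlib 3.10.9, and tables were read with pandas 2.3.3 in Python 3.11.15.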

Results

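Leukaemic cells driven by NRAS and AE9a were profiled by RNA-seq after growth in mice, in 2 libraries from wild-type donor cells and 2 labelled Tet2 KO. Estimated depth was 18.6 to 23.8 M reads. Between 11300 and 11467 genes reached 1 TPM in each library. The WT libraries differed by about the sampling noise of their reads over most genes, apart from 29 of 4670 genes, and were counted as 1 sample. For the genes with the most estimated reads, the variance between them was 1.90 times that of read sampling. WT values are the mean of both libraries (n = 1), and Tet2 KO values are means ± SD (n = 2).

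Several features of the libraries moved with the labels. ERCC spike-ins took 4.66% and 4.62% of TPM in the WT libraries and 2.95% and 3.19% in those labelled Tet2 KO. Rn45s, a ribosomal RNA precursor, took 0.923% and 0.894% in WT and 0.134% and 0.298% in the others. The 20 most abundant genes took 11.8% in each WT library, against 22.2% and 19.9%. Xist, expressed from the inactive X chromosome of female cells, stood at 0.34 TPM in each WT library and at 86.1 and 28.2 TPM in the libraries labelled Tet2 KO. The Y-linked gene Eif2s3y was present in all 4, at 107 and 107 TPM in WT and 29.8 and 90.4 TPM in the others. Of the 5 sex-linked genes tested, 0 passed limma's threshold over all genes, 0 adjusted over the list alone, and 1 had an unadjusted p under 0.05. With both WT libraries as samples, the design fixed in advance, 1 of them was called higher and 1 lower. Across genes with at least 5 TPM in all libraries, Pearson's r of log2 TPM between the groups was 0.77 to 0.80; genes are not independent replicates.

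The targeted gene was examined first. Tet2, a dioxygenase that oxidises 5-methylcytosine (chromosome 3, 133463679 to 133545139, minus strand, mm10), was not lower in the libraries labelled Tet2 KO. It stood at 43.5 and 43.7 TPM in the WT libraries and at 63.7 and 68.1 TPM in the others, a log2 change of 0.58 ± 0.19 (limma adjusted p = 0.0171). This call was lost without the abundance trend and robust estimation (adjusted p = 0.0713) and without the filter on low values (adjusted p = 0.117). Adjusted p ranged from 6.28e-05 to 0.117 over all alternatives. A value for the whole gene does not show a deleted exon, and the labels do not give the allele, so it neither checks the deletion nor excludes it. All directions given rest on the labels. Its paralog Tet3 rose from 35.9 to 126 ± 6.75 TPM (adjusted p = 1.48e-06), while Tet1 stayed at or under 0.05 TPM in each library. Of 14 tested TET and DNA methylation enzymes, 7 rose and 1 fell, with 7 and 1 adjusted over the list alone. Risers included Gadd45a, a DNA damage response gene, at 3.30 ± 0.19 on the log2 scale, Idh1 at 1.66 ± 0.20 and the maintenance methyltransferase Dnmt1 at 0.93 ± 0.21. The de novo methyltransferase Dnmt3b fell by 1.10 ± 0.29, from a low level of 4.51 to 1.59 ± 0.410 TPM. With ERCC scaling its log2 change was -0.68. The list's median was 0.45, or 1.00 with ERCC scaling (camera adjusted p = 0.0251; adjusted p = 0.73 with an estimated correlation), and the call was lost with ERCC scaling and without the filter.

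The comparison asked which genes differ between leukaemic cells made from Tet2 knockout and from wild-type donors. In the libraries labelled Tet2 KO, 22 of 23 neutrophil granule genes rose, with a median log2 change of 4.61, and 37 of 37 interferon-induced genes fell, with a median of -4.63. Of 11919 genes tested, 2629 were higher and 3182 lower, so that 45.2% of calls were higher. At least 8-fold changes made up 255 of the higher and 270 of the lower calls. Among the 10 largest rises were 5 genes of the stefin cluster of cysteine protease inhibitors on chromosome 16 (Stfa3, Stfa1, Stfa2l1, Stfa2 and BC100530). Stfa1 (chromosome 16, 36276951 to 36285373) went from 40.3 to 11113 ± 544 TPM. These copies are near-identical, so the split of reads between them is uncertain. The others were Retnla, a secreted resistin-like protein (0.09 to 328 ± 31.4 TPM), the phospholipase Pla2g7, the neutrophil chemokine receptor Cxcr2 (2.58 to 566 ± 78.2 TPM), Tinagl1 and Padi4, which citrullinates histones in neutrophils. The 10 largest falls were Ifi205, Mx1, Ifit3, Ifit2, Tgtp2, Ccl22, Phf11b, Mx2, Ifit3b and Cx3cl1. Ifi205 went from 1388 to 3.77 ± 0.417 TPM, the chemokine Ccl22 from 408 to 1.71 ± 0.424 TPM and Cx3cl1 from 212 to 1.01 ± 0.495 TPM. The fall of Tgtp2 did not pass with a pseudocount of 0.1. Scaled to the ERCC total, a choice made after seeing the data, 4942 genes were higher and 1492 lower, so 76.8% of calls were higher, and the median of all genes moved from -0.12 to 0.43. Without the filter 123 and 295 passed, and 100 of the 111 tested named genes other than Tet2 lost their call; with both WT libraries as samples 3520 and 4517 passed, and leaving out Tet2 KO replicate 1 or 2 moved the lower calls to 4995 or 5687.

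**Figure D1:**
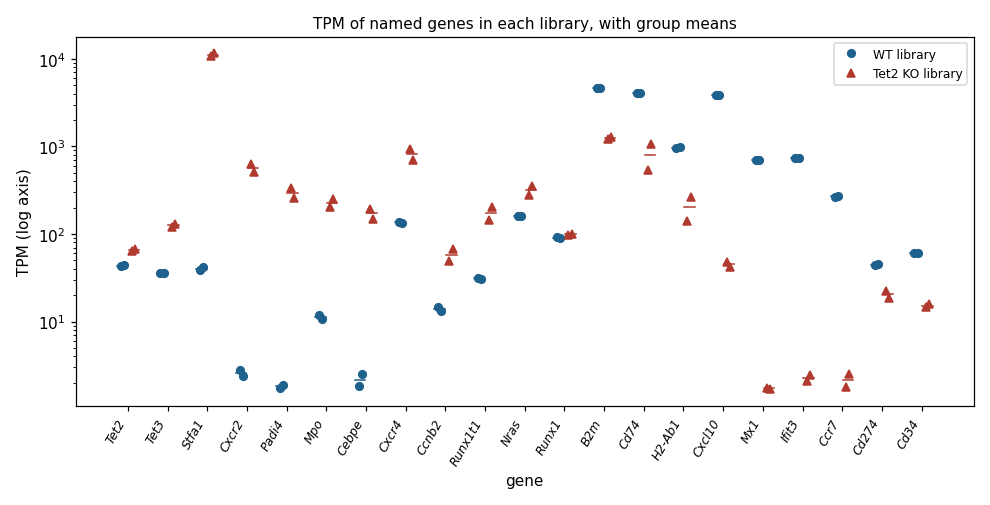
TPM on a log axis for 21 named genes in each library, with WT as circles, the libraries labelled Tet2 KO as triangles and group means as short lines. Stfa1, Cxcr2 and Padi4 stand higher in the libraries labelled Tet2 KO, Mx1, Ifit3 and Ccr7 lower, and Tet2 is not lower there.

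Every tested member of the interferon response list, 37 of 37, fell in the libraries labelled Tet2 KO, with 37 adjusted over the list alone. The median change was -4.63 (camera adjusted p = 5.25e-23; adjusted p = 0.73 with an estimated correlation), and -4.06 with ERCC scaling. The antiviral GTPase gene Mx1 (chromosome 16, 97447035 to 97462907) went from 694 to 1.74 ± 0.0354 TPM, Ifit3 (chromosome 19, 34583531 to 34588731) from 733 to 2.28 ± 0.255 TPM and Rsad2, which encodes viperin, from 917 to 10.8 ± 1.29 TPM. Of 18 sensors and regulators of nucleic acid sensing, 14 fell and 2 rose, with 14 and 2 adjusted over the list alone. Their median was -2.01 (camera adjusted p = 2.36e-05; adjusted p = 0.73 with an estimated correlation). The exonuclease Trex1 went from 574 to 24.5 ± 4.73 TPM, Ddx58, which encodes RIG-I, from 134 to 12.0 ± 0.707 TPM and Tlr9 from 199 to 26.7 ± 0.721 TPM. Ddx58, Ifih1 and Zbp1 are also in the interferon response list. The DNA sensor Aim2 rose from 86.8 to 136 ± 13.2 TPM (adjusted p = 0.0172), a call lost without trend and robust estimation.

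Antigen presentation genes fell. In MHC class I presentation 16 of 19 members fell and 0 rose, with 18 lower adjusted over the list alone, and the median was -2.24 (camera adjusted p = 7.23e-08; adjusted p = 0.73 with an estimated correlation). The peptide transporter Tap1 (chromosome 17, 34187553 to 34197225) fell by 3.15 ± 0.19, and the immunoproteasome subunits Psmb9 and Psmb8 fell by 3.29 ± 0.21 and 2.93 ± 0.21. B2m, the shared light chain of class I molecules, went from 4632 to 1249 ± 59.6 TPM, and H2-K1 from 1976 to 649 ± 11.8 TPM. H2-D1 fell by 1.05 ± 0.28 (adjusted p = 0.00588), but not past the threshold with ERCC scaling or quantile normalization. H2 genes have close paralogs, which makes their separate values uncertain. In MHC class II presentation 12 of 15 members fell and 0 rose, with 13 lower adjusted over the list alone. The median was -1.94 (camera adjusted p = 9.15e-05; adjusted p = 0.73 with an estimated correlation). The invariant chain Cd74 stood at 4024 TPM in WT and at 541 and 1074 TPM in the libraries labelled Tet2 KO. H2-Ab1 went from 968 to 203 ± 87.2 TPM, and the class II transactivator Ciita from 3.93 to 1.51 ± 0.651 TPM (adjusted p = 0.0141), which did not pass with ERCC scaling or quantile normalization.

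Inflammatory mediators moved both ways, with more falls. Of 27 chemokines and inflammatory cytokines, 16 fell and 6 rose (17 and 6 adjusted over the list alone). Their median was -1.001, or -0.83 with ERCC scaling (camera adjusted p = 0.00432; adjusted p = 0.73 with an estimated correlation). Cxcl10, an interferon-induced T cell chemokine, went from 3894 to 45.0 ± 4.81 TPM, Cxcl16 from 1117 to 34.0 ± 4.53 TPM and Ccl5 from 455 to 16.5 ± 1.22 TPM, whereas the neutrophil chemokine Cxcl2 rose from 22.4 to 543 ± 21.5 TPM. Among 24 NF-kB targets 20 fell and 1, Cxcl2, rose, with 20 and 1 adjusted over the list alone. Their median was -1.34, or -0.75 with ERCC scaling (camera adjusted p = 1.08e-05; adjusted p = 0.73 with an estimated correlation). Ptgs2, which encodes COX-2, fell by 4.12 ± 0.28 and Traf1 fell by 3.17 ± 0.20. Tnf, Il1b and Cxcl2 are in both this list and that of chemokines, and Cxcl9 and Cxcl10 are in the chemokine and interferon lists. Of 18 costimulatory and NK receptor ligands 11 fell and 3 rose, with 11 and 3 adjusted over the list alone. Tnfsf9, the ligand of 4-1BB, went from 277 to 10.7 ± 2.00 TPM and Cd86 from 103 to 42.1 ± 8.99 TPM, while the NKG2D ligand Raet1d rose from 9.27 to 38.6 ± 3.31 TPM. That list's median was -1.22, or -0.63 with ERCC scaling (camera adjusted p = 0.0222; adjusted p = 0.73 with an estimated correlation), a call lost with both WT libraries as samples, without Tet2 KO replicate 1 or 2 and without the filter. Inhibitory ligands and enzymes did not pass as a list: of 21, 6 rose and 8 fell (6 and 10 adjusted over the list alone), with a median of -0.26, a mean of 0.16 and, with ERCC scaling, a median of 0.33 (camera adjusted p = 0.889). Among them Cd274, which encodes PD-L1, went from 44.5 to 20.6 ± 2.66 TPM (adjusted p = 0.000930), and the phagocytosis checkpoint ligand Cd47 from 317 to 205 ± 0.509 TPM (adjusted p = 0.0265). With ERCC scaling neither passed, and Cd47 also did not with quantile normalization, median centring or limma without trend and robust estimation. The same list held larger rises, picked after their values were seen, with log2 changes of 5.60 for Arg1, 4.09 for Ceacam1 and 3.93 for Cd24a. Its largest fall was that of Lgals9, at -2.70.

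Neutrophil granule genes formed the list with the largest rise. Of 23 members 22 rose and 0 fell, with 23 higher adjusted over the list alone, at a median of 4.61 (camera adjusted p = 8.60e-15; adjusted p = 0.73 with an estimated correlation). S100a9 and S100a8, named after their values were seen, reached 38264 and 33970 TPM and 35305 and 27010 TPM in the libraries labelled Tet2 KO, from WT means of 633 and 520 TPM. Padi4 (chromosome 4, 140745865 to 140774236) went from 1.82 to 294 ± 55.4 TPM and Wfdc21 from 9.96 to 283 ± 22.1 TPM. Primary granule genes, made earlier in granulocyte development, rose in 14 of 19 cases and fell in 2 (14 and 3 adjusted over the list alone). Their median was 2.68 (camera adjusted p = 9.19e-06; adjusted p = 0.73 with an estimated correlation). Mpo, which encodes myeloperoxidase, went from 11.3 to 228 ± 35.4 TPM and Cebpe, a factor of granulocyte maturation, from 2.17 to 172 ± 32.1 TPM. Clec12a, an inhibitory myeloid receptor, fell by 2.03 ± 0.23. In the same libraries ERCC took 2.95% and 3.19% of TPM, against 4.66% and 4.62% in WT, and Xist stood at 86.1 and 28.2 TPM, against 0.34 TPM.

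Markers of other cell types differed too. Of 10 dendritic cell genes 9 fell and 0 rose, with 9 adjusted over the list alone, at a median of -1.52 (camera adjusted p = 0.000353; adjusted p = 0.73 with an estimated correlation). Without the filter that call was lost. The list held 17 genes, and those left untested were low in WT, such as Clec9a at 0.13 and 0.31 TPM and Cd209a at 0.28 and 0 TPM. Among tested members, Siglech stood at 1.48 and 1.38 TPM and Xcr1 at 4.62 and 5.12 TPM in WT, against 79.4 and 80.4 TPM for Itgax. The list's fall thus does not show that dendritic cells were present in WT. Ccr7, a homing receptor of mature dendritic cells, went from 270 to 2.17 ± 0.523 TPM and the cytokine receptor Flt3 from 70.2 to 2.54 ± 0.127 TPM. Mast cell and basophil genes rose in 8 of 9 cases and fell in 1 (8 and 1 adjusted over the list alone), at a median of 1.71 (camera adjusted p = 0.000353; adjusted p = 0.73 with an estimated correlation). Cpa3, a mast cell protease, went from 0.375 to 24.9 ± 5.68 TPM, while Il3ra fell by 1.21 ± 0.20. The member with the smallest p, Hdc, is also in the primary granule list. Of 5 erythroid genes 4 rose (4 adjusted over the list alone), such as Hbb-bt from 0.61 to 6.28 ± 2.77 TPM and the transferrin receptor gene Tfrc from 8.54 to 25.9 ± 0.856 TPM; Car1 was listed at 0 in both WT libraries. Their median was 2.07 (camera adjusted p = 0.0121; adjusted p = 0.73 with an estimated correlation), and ERCC scaling ended that call.

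Other cell type lists did not pass. Of 22 monocyte genes 6 rose and 12 fell (6 and 12 adjusted over the list alone; median -1.13, or -0.54 with ERCC scaling, camera adjusted p = 0.0694). They passed with ERCC scaling and without WT replicate 1 or 2. Of 13 red pulp and tissue macrophage genes 2 rose and 7 fell (4 and 7 adjusted over the list alone; median -0.97, or -0.37 with ERCC scaling, camera adjusted p = 0.133). They passed with ERCC scaling, with a filter of 5 TPM and without WT replicate 1 or 2. Of 10 T cell genes 2 rose and 3 fell (2 and 3 adjusted over the list alone; median 0.033, or 0.33 with ERCC scaling, mean -0.26, camera direction lower, adjusted p = 0.889), and the median was negative without any 1 library. Of 7 megakaryocyte genes 4 rose and 2 fell (4 and 2 adjusted over the list alone; median 0.90, or -0.18 without Tet2 KO replicate 2, camera adjusted p = 0.349), and of 7 stroma and endothelium genes likewise 4 and 2 (4 and 2 adjusted over the list alone; median 0.47, or 1.06 with ERCC scaling, camera adjusted p = 0.328). NK cell, B cell and plasma cell lists had 3 tested members each, too few for the list test, with 0, 2 and 1 higher and 3, 1 and 2 lower, and the same counts adjusted over the list alone.

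**Figure D2:**
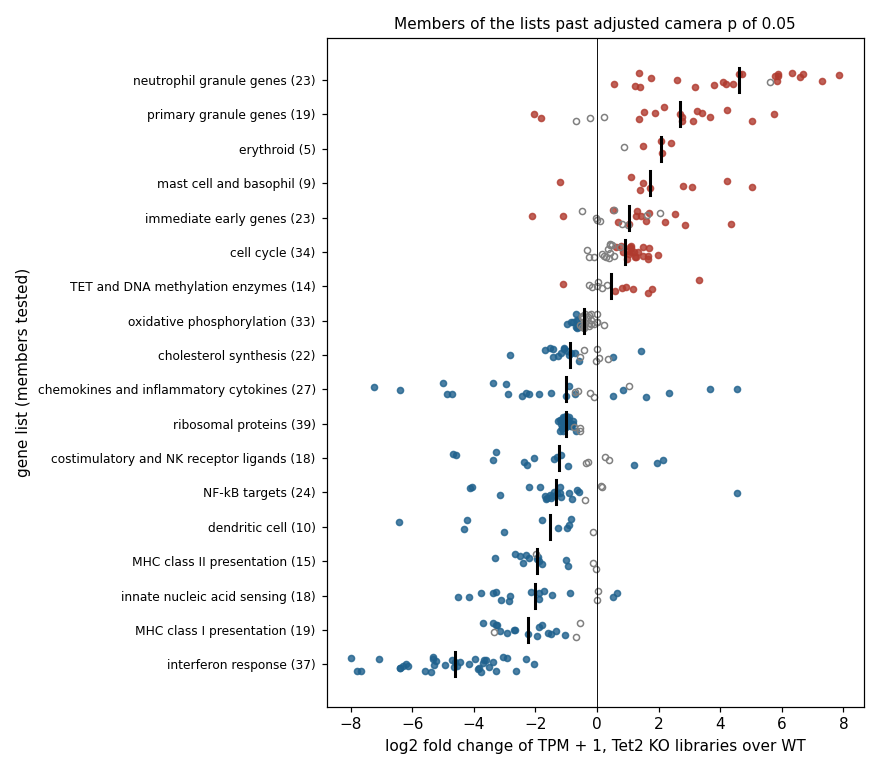
Log2 fold change of TPM + 1 of each tested member (points) and the median (black bar) in the 18 lists past an adjusted camera p of 0.05. That threshold applies at the preset correlation, and none of these lists passed with an estimated correlation. The latter test found a list moved by 2-fold in 0 of 10 simulated runs, so not passing it says little about a list. Filled points passed the limma test over all genes, coloured by the direction of the list's median, and open grey points did not; medians run from -4.63 for the interferon response to 4.61 for neutrophil granule genes, and that of oxidative phosphorylation (-0.43) turns to 0.14 with ERCC scaling.

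In the cell cycle list 20 of 34 members rose and 0 fell, with 20 adjusted over the list alone, at a median of 0.90, or 1.48 with ERCC scaling (camera adjusted p = 1.31e-05; adjusted p = 0.77 with an estimated correlation). The mitotic cyclin Ccnb2 went from 13.9 to 58.2 ± 12.1 TPM and Cdc20 from 12.6 to 42.0 ± 8.53 TPM. Immediate early genes, induced within minutes by many stimuli, rose in 12 of 23 cases and fell in 2 (12 and 2 adjusted over the list alone), at a median of 1.04, or 1.63 with ERCC scaling (camera adjusted p = 0.000333; adjusted p = 0.77 with an estimated correlation). Fosb went from 6.43 to 156 ± 52.1 TPM and Egr1 from 7.63 to 61.8 ± 9.53 TPM, whereas the phosphatase Dusp2 fell by 2.11 ± 0.20. Of 19 stem and progenitor genes 7 rose and 8 fell (7 and 8 adjusted over the list alone), with a median of 0.00034 and a mean of -0.09 (camera adjusted p = 0.890); the median was -1.50 with a filter of 5 TPM and 0.56 with ERCC scaling. Cd34 fell by 1.92 ± 0.22, Kit, a stem cell factor receptor, rose from 0.835 to 2.07 ± 0.191 TPM, a call lost without WT replicate 2, and Hoxa9 and Meis1 were at or under 0.32 TPM in each library. Of 21 homing and adhesion genes 6 rose and 8 fell (6 and 8 adjusted over the list alone; median -0.019, mean 0.16, and a median of 0.57 with ERCC scaling, camera adjusted p = 0.889). The chemokine receptor Cxcr4 went from 135 to 817 ± 172 TPM, and the tetraspanin Tspan13 fell by 2.66 ± 0.28. Of 17 RAS-MAPK output genes 7 rose and 6 fell (8 and 6 adjusted over the list alone; median 0.40, or 0.98 with ERCC scaling, camera adjusted p = 0.339), and of 22 p53 targets 8 rose and 9 fell (8 and 9 adjusted over the list alone; median -0.27, mean 0.22, and a median of 0.17 with ERCC scaling, camera direction higher, adjusted p = 0.889).

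The loci behind the transgenes were examined because TPM pools transgene and endogenous reads where their sequence is shared. Runx1t1, whose human counterpart gives AE9a its ETO part, went from 31.2 to 176 ± 41.8 TPM (log2 change 2.43 ± 0.23, adjusted p = 1.23e-06). Nras rose by 0.97 ± 0.24 on the log2 scale, from 160 to 316 ± 56.7 TPM (adjusted p = 0.00316). Runx1 stood at 91.0 and 99.6 ± 1.77 TPM, a log2 difference of 0.13 ± 0.19 (adjusted p = 0.607) that passed with ERCC scaling (0.72) and without Tet2 KO replicate 1 or 2. Adjusted over the list alone, 2 of the 3 were higher.

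Ribosomal protein genes fell in 36 of 39 cases and rose in 0 (37 lower adjusted over the list alone), at a median of -1.01 (camera adjusted p = 2.36e-05; adjusted p = 0.77 with an estimated correlation). With ERCC scaling the median was -0.41, and Rps20 and Rpl14 no longer passed. Cholesterol synthesis genes fell in 14 of 22 cases and rose in 2 (14 and 2 adjusted over the list alone), at a median of -0.87, or -0.34 with ERCC scaling (camera adjusted p = 0.0177; adjusted p = 0.73 with an estimated correlation). That call was lost without the filter and without Tet2 KO replicate 2. Sqle, which encodes squalene epoxidase, went from 47.2 to 14.2 ± 2.32 TPM, while Sc5d rose from 28.1 to 76.9 ± 1.02 TPM. Oxidative phosphorylation genes fell in 11 of 33 cases (9 adjusted over the list alone), at a median of -0.43 (camera adjusted p = 0.00931; adjusted p = 0.86 with an estimated correlation), which turned to 0.14 with ERCC scaling and lost its call. Without WT replicate 1 or 2 it did not pass either. Glycolysis genes did not pass as a list (3 higher and 9 lower of 24, also adjusted over the list alone; median -0.40, or 0.20 with ERCC scaling, camera adjusted p = 0.395). Neither did the unfolded protein response (4 and 10 of 24, 5 and 11 adjusted over the list alone; median -0.60, or -0.0050 with ERCC scaling, camera adjusted p = 0.244), which passed without WT replicate 2, or RNA methylation enzymes (4 and 3 of 21, also adjusted over the list alone; median -0.0064, or 0.57 with ERCC scaling, camera direction higher, adjusted p = 0.972).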

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

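Scaling to ERCC, rescaling without ERCC and Rn45s, and the combinations with both WT libraries as samples were chosen after seeing the data; that fit itself was the design fixed in advance. Counts of genes stayed within 1.5 times of 2629 higher and 3182 lower except as follows. Without the filter they were 123 and 295, with a fold threshold of 1.5 they were 1302 and 1361, with at least a 2-fold change 1698 and 1906, and with ERCC scaling 4942 and 1492. Leaving out 1 library gave 2750 to 3803 higher and 2964 to 5687 lower; the upper ends leave 1 Tet2 KO library, so that the spread comes from the WT pair alone. The cause of the drop without the filter was not tested; 100 of 111 named genes lost their call there. Tet2 kept its log2 change of 0.58 but lost its call there and without trend and robust estimation. Lists called numbered 7 higher and 11 lower. With camera's estimated correlation they were 0 and 0, also with both WT libraries as samples (0 lists, or 1 there, had an unadjusted p under 0.05), and with fry 2 and 2, or 11 and 13 with both WT libraries as samples. With WT as 1 sample, camera's estimated correlation also found the moved list in 0 of 10 simulated runs. Its counts here therefore say little about the lists. Without 1 WT library 11384 or 11385 genes were tested, as genes found in WT alone drop out. The numbers are not shown to pair libraries: deviations of same-numbered libraries correlated at -0.01 (Pearson) over 2 pairs. With the replicate block and both WT libraries as samples, 3495 genes were higher and 4461 lower. Signs turned, with no call on either side unless stated. With ERCC scaling the medians were 0.57 for RNA methylation, 0.33 for inhibitory ligands, 0.57 for homing, 0.17 for p53 targets, 0.20 for glycolysis and 0.14 for oxidative phosphorylation, which lost its call, and Cenpa was at 0.31. Under quantile normalization RNA methylation and homing stood at 0.031 and 0.0043, and under median centring at 0.092 and 0.079. The stem and progenitor median was -1.50 with a filter of 5 TPM and -0.032 rescaled without ERCC and Rn45s. Leaving out 1 library gave medians of -0.28 to 0.042 for homing, -1.30 to 0.095 for stem and progenitor genes, -0.57 to -0.0022 for T cell genes and -0.18 to 0.99 for megakaryocyte genes. The cause was not tested. Over named genes and alternatives 1391 results kept direction and side of the threshold, 124 lost and 6 gained a call and 1 turned; for lists 449, 65, 17 and 20 did. Alternatives for count tables were not run, since the values are TPM. Estimated depth limits genes near 1 TPM most.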

Other observations

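All tests of explanations below were chosen after the results were seen. The genes named first were also chosen after their values were seen. Members of the macrophage and monocyte lists went both ways in the libraries labelled Tet2 KO. The complement genes C1qa, C1qb and C1qc fell, with log2 changes of -2.86, -3.04 and -3.34, and so did the scavenger receptor gene Cd163, at -3.26. Apoe, a lipid carrier, rose from 39.7 to 700 and 779 TPM. The arginase gene Arg1, which is in the inhibitory ligand list instead, rose from 1.08 to 96.4 and 103 TPM. The fractalkine receptor Cx3cr1 fell by 6.62 and the monocyte Fc receptor Fcgr1 fell by 5.04 on the log2 scale, whereas Fcgr3 rose by 1.85 and the matrix gene Fn1 by 3.36. In the T cell list, Il7r, a lymphoid cytokine receptor, went from 213 to 20.9 and 25.8 TPM. In the stroma and endothelium list, Flt1, a VEGF receptor, went from 1.05 to 40.6 and 32.4 TPM. Each passed the limma threshold.

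Interferon and antigen presentation genes fell while granule genes rose. Loss of TPM share to a few abundant genes was argued against: with ERCC scaling the interferon median remained at -4.06. Dilution by mature neutrophils alone in the libraries labelled Tet2 KO would lower cell cycle genes by as much, if the other cells cycled as in WT. The cell cycle median was 0.90, which argues against dilution as the whole cause under that condition. The condition was not tested, and a part played by dilution stays open. Red pulp macrophages in the WT libraries were argued against by their abundant transcripts Cd5l, Slc40a1, Vcam1 and Spic, whose highest WT mean was 2.43 TPM. Other members of that list were abundant in the WT libraries, such as Hmox1 at 2299 and 2319 TPM and C1qb at 367 and 380 TPM. The argument therefore covers only macrophages rich in the former transcripts. CD45.2 enrichment would reduce recipient cells, but its purity is not known. For the granule genes, mature neutrophils in the libraries labelled Tet2 KO may contribute, and this cannot be told apart from expression in the leukaemic cells, since the higher Runx1t1 (2.43) has no known level per cell and 21 of the 23 granule genes reached 1 TPM in both WT libraries; other macrophages or dendritic cells in WT, donor genotype, animal and the single WT sample stay open, untested.

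Pancreas genes appeared in 3 of the 4 libraries. Over 25 acinar and 14 islet genes, a list written after the genes were seen, the total was 326 TPM in WT replicate 1, 221 and 320 TPM in the libraries labelled Tet2 KO and 5.18 TPM in WT replicate 2, where 7 of the 39 genes were above 0. Ins2, which encodes insulin, stood at 137, 95.2, 138 and 0 TPM in that order. Pancreas tissue in an RNA that both WT libraries share is argued against by a total in WT replicate 2 of 1.59% of that in WT replicate 1; this rests on both coming from about 1 RNA, and tissue in the Tet2 KO samples stays open. Reads from pancreas libraries handled alongside are a candidate explanation: the ratio of islet to acinar TPM was 2.89, 2.54 and 3.70, at most 1.46-fold apart between the 3 libraries, which does not exclude tissue there; no biological explanation was tested.

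Xist and Y-linked genes occurred together in the libraries labelled Tet2 KO, with 4 Y-linked genes at medians of 24.2% and 68.4% of the WT level. Neutrophils of the other sex as the sole source of granule transcripts in these libraries were argued against. Xist differed between replicates 1 and 2 by 1.57 on the log2 scale, but the neutrophil list by a median of 0.23. A part from such cells stays open, since granule transcripts from other cells would flatten that difference. WT cells mixed into the libraries labelled Tet2 KO were argued against by interferon genes at a median of 4.51% of the WT level in replicate 2 and at most 25.0%. Donor cells of both sexes stay open, untested. So do recipient cells, which CD45.2 enrichment would reduce but, at an unknown purity, need not remove. The labels do not give sex.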
